A study of Homo sapiens with 6 samples.

How the data were processed

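Total RNA of the osteosarcoma lines 143B and HOS, 3 biological replicates each, was taken in Trizol after 24 hours on wells coated with 1 mL of Matrigel, and biotinylated RNA made from 6 ug of it was hybridised to Affymetrix arrays, per the labels' protocols. The array type is not given in the sources used here. The authors deposited log2 signals made by RMA (robust multi-array average), per the submitters' processing notes, whose version and options are not given in the sources used here. The series value table and the submitters' annotated workbook hold 70523 rows each, with the same values in all 70523 to within 5e-07. The values reach 19.93 on every array, above the log2 of a 16-bit scan (16), so the signals were rescaled in a way the sources used here do not give, and folds near that top are uncertain. Array medians over all rows were 3.77 to 3.84.

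Of these rows, 2995 were control rows and 67528 of the main category, of which 40310 had no gene symbol and 27218 had exactly 1. Symbols were updated through the reference gene table: 2941 rows were named by accession, 22645 held a current symbol, 475 were matched through an older symbol and 1157 kept the symbol of the file. In 27 rows a spreadsheet had turned the symbol into a date, and 26 of these were recovered by accession. Where a gene had several rows, as 728 genes did, the row with the highest mean over all 6 samples was used. This gave 25425 genes, 18990 protein-coding and 6435 non-coding. Positions are those of the workbook, whose descriptions name GRCh37 for 16145 rows. No detection calls were used, so the background level was set at the 95th percentile of the means of 407 olfactory receptor genes, 4.09. A gene whose means lay under it in both lines is given without a fold. Where only 1 line lay under it, the fold is the mean of the brighter line over the background level and is written as a lower bound. At the top of the scale, 4 genes held the highest value on all 6 arrays.

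The lines were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, line as the only term, two-sided, Benjamini-Hochberg adjustment over all genes tested). A gene was called at an adjusted p below 0.05 and an absolute log2 difference of at least 1. The 25 gene lists, fixed before the data were examined, were tested with camera at an inter-gene correlation of 0.01 and again with the correlation estimated per list, and with fry. Of their members, BGLAP, TIMP2, BUB1B, MAGEA2, MAGEB4, SSX2, HOXB3, HOXB4 and HOXD4 had no row under those symbols. Differences are 143B minus HOS throughout. Errors are SDs of 3 replicates for levels and limma's standard errors for differences. An exact permutation test of 3 samples against 3 cannot give a two-sided p below 0.1, so only the model's p-values are given. The labels call the replicates biological but do not say whether they came from separate cultures, and p-values measure the spread between these samples.

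The genes named were chosen by a rule written before the data were examined: the 6 largest rises and the 6 largest falls among called genes whose groups did not overlap, leaving out uncharacterised loci, pseudogenes and short non-coding RNAs such as snoRNAs, snRNAs and microRNAs (antisense and intronic transcripts, 5S rRNA and other short RNA classes were added to these when the rule was coded), so that all of the 12 are coding genes and some snoRNAs fell further; for each list the 2 called members with the largest difference, plus the largest the other way; and further genes whatever their result, among them CDH5, EPHA2, MMP2, MMP9, MMP14, VEGFA, KDR, PECAM1 and TK1. Some genes that the rule takes are not reported here. Other members of a list, named where few were called or as further examples, were chosen after their values were seen. On data simulated from the real means and spreads of the 25425 genes for 143B against HOS, with 200 genes changed, 98 of 100 genes changed by 1.5 on the log2 scale were called and 99 of 100 changed by 3, with 0 false calls. All other genes were given no difference and no batch effect, and a call needs a log2 difference of at least 1. The count of 0 was therefore largely fixed in advance. In a simulation of the 25 lists with YAP-TEAD targets shifted by -1, that list was called and 0 others were. The simulated genes varied independently of each other, so this does not show how often lists of correlated genes are called falsely.

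Alternatives were planned before the data were examined: the workbook's values, quantile normalization, median centring, filters on dim genes, trend and robust variance, array weights, the mean of a gene's rows, the replicate number as a block, each sample left out in turn, all rows, no minimum on the difference, TREAT, a test per gene, and other set tests. Cyclic loess, protein-coding genes only and genes outside the chromosome segments were added after seeing the data. Gene Ontology terms of the workbook with 10 to 300 genes were tested for enrichment among called genes above the background (hypergeometric, one-sided, Benjamini-Hochberg over 4286 tests). For a few enriched terms the expected count was also taken from genes of the same signal group, out of 10 groups, with 10000 random draws. This was added after seeing the data. Runs of neighbouring genes were sought among 11400 coding genes above the background in windows of 10, against 1000 random gene orders. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for tables, tests and figures.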

Results

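RNA from human osteosarcoma cell lines cultured on Matrigel, a basement membrane gel, was measured on Affymetrix arrays. Per the labels, 143B carries the vasculogenic mimicry phenotype, in which tumour cells line up into vessel-like channels without endothelial cells, and HOS does not. 143B is known as a transformed, thymidine-kinase-negative derivative of HOS, so the lines share an origin. Each line had 3 biological replicates, all taken after 24 hours on the gel; the series description speaks of duplicates, while the sample labels number 3 per line. There were no samples grown without Matrigel, so the comparison is of the lines on the gel and not of the response to it. Levels are deposited log2 signals, and 25425 genes were tested. The number of arrays, 3 per line, limits the precision of each value. A level of 4.09, reached by few olfactory receptor genes, served as the background, and 13829 genes had a mean above it.

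The replicates of a line resembled each other far more than the other line. Pearson's r across genes, which are not independent replicates, was 0.997 to 0.998 within lines and 0.959 to 0.962 between lines. The first principal component held 92.8% of the variance and separated the lines, and the next held 2.45%, with replicate 3 of 143B at the opposite end from replicate 1. The lines also differed in control transcripts that are spiked into RNA before labelling. The poly-A control dap had a mean of 3.90 ± 0.37 (SD, n = 3) in 143B and 8.78 ± 0.06 (SD, n = 3) in HOS, and the median difference of the 4 poly-A controls was -3.55 on the log2 scale. The hybridization controls, added after labelling, differed by a median of -0.20. The poly-A controls split exactly by line, so a batch effect, if there was one, cannot be told apart from the group in any of the differences given here.

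**Figure D1:**
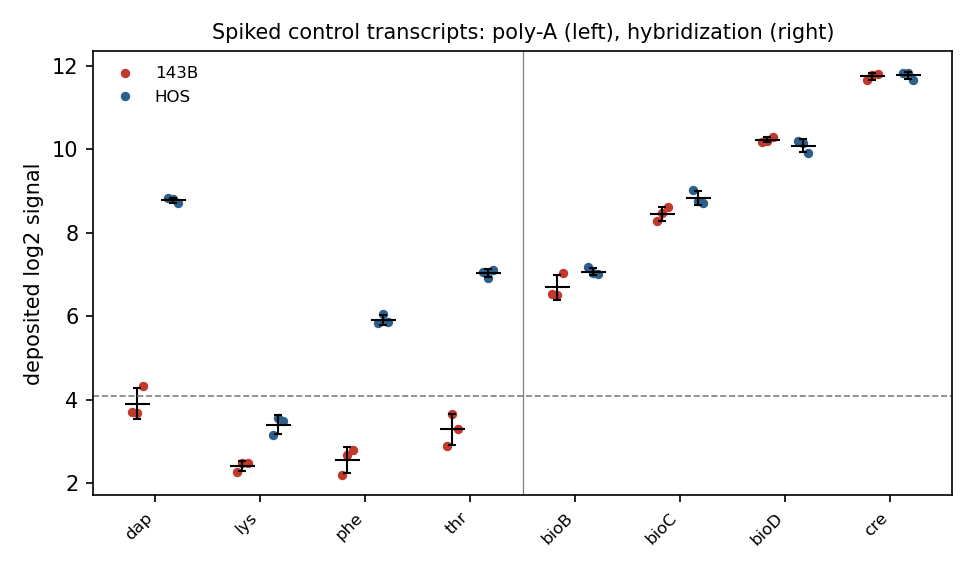
Deposited log2 signal of spiked control transcripts on the 3 arrays of 143B (red) and the 3 of HOS (blue); the black bars are means with SD and the dashed line is the background level of 4.09. The poly-A controls dap, phe and thr lie above the background in HOS and below it in the mean of 143B, whereas the hybridization controls differ by -0.38 to 0.14.

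The first question was which genes set the line with vasculogenic mimicry apart from the line without it. The largest rise in 143B was in MMP1, the interstitial collagenase, at 19.23 ± 0.01 in 143B against 8.79 ± 0.14 in HOS (SD, n = 3), a log2 difference of 10.44 (SE 0.08, adjusted p = 1.80e-08). The 143B value lies near the top of the scale, 19.93, which is above the log2 of a 16-bit scan, so the size of this difference depends on a scaling step that is not given in the sources used here. ITGA2, the collagen-binding integrin subunit alpha-2, was higher by 8.73 (SE 0.07, adjusted p = 2.42e-08). With non-coding RNAs left aside, TBX15, a T-box transcription factor of skeletal development, was higher by 6.85, the sushi-repeat protein gene SRPX by 6.12 and ANPEP, which encodes aminopeptidase N, by 6.09. The ion channel gene TRPA1 was under the background in HOS and at 10.88 ± 0.17 (SD, n = 3) in 143B, at least 110-fold higher. The largest fall was in MYL9, a regulatory light chain of non-muscle and smooth muscle myosin, at 7.18 ± 0.27 in 143B against 14.67 ± 0.14 in HOS (SD, n = 3), a log2 difference of -7.48 (SE 0.14, adjusted p = 2.54e-07). With short non-coding RNAs left aside, TNFRSF10D, a decoy receptor for the death ligand TRAIL, differed by -5.27, the proteoglycan gene SRGN by -4.95, the ubiquitin ligase adaptor gene WSB1 by -4.90 and the fatty acid elongase gene ELOVL2 by -4.78. INA, which encodes the neuronal intermediate filament protein internexin, was under the background in 143B and at least 23.5-fold higher in HOS.

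In limma, 2808 of the 25425 genes differed at an adjusted p below 0.05 and at least 2-fold, 1234 higher and 1574 lower in 143B. The adjusted p alone was met by 11763 genes, 5280 higher and 6483 lower. The groups did not overlap in 58.0% of the genes, where chance gives 10%, nor in any of the 2808 called genes. Of these, 2181 were protein-coding and 627 non-coding, and 68 differed at least 16-fold. A test against the 2-fold minimum itself (TREAT) called 1662 genes, 730 higher and 932 lower. The balance of directions depends on the scaling, with 1365 higher and 1361 lower after quantile normalization and 1416 higher and 1311 lower after cyclic loess, an alternative chosen after seeing the data. Because line and phenotype coincide, and the poly-A controls split by line too, these counts cannot be assigned to the phenotype alone.

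A second question was whether genes tied to vasculogenic mimicry, blood vessels and their wall cells differed. Among 40 measured mediators of vasculogenic mimicry, 8 were higher in 143B, 9 lower and 23 not called, and the list as a whole did not pass (camera, adjusted p = 0.740). NRP1, a co-receptor for vascular endothelial growth factor, was higher by 3.88 (SE 0.07, adjusted p = 2.54e-07), and MMP14, a membrane-bound matrix protease, was higher by 1.66 (SE 0.07, adjusted p = 4.24e-06). PDGFRB, the receptor for platelet-derived growth factor B, was lower by a log2 difference of -3.01, and EPHA2, an ephrin receptor kinase, by -1.72 (SE 0.06, adjusted p = 1.81e-06). Several genes often linked to the phenotype did not reach the 2-fold minimum. CDH5, which encodes vascular endothelial cadherin, had means of 3.56 in 143B, under the background, and 4.12 in HOS, barely above it (adjusted p = 0.000381). The gelatinase gene MMP9 differed by 0.42 (adjusted p = 0.0039), with means of 4.65 in 143B and 4.23 in HOS, near the background. The growth factor gene VEGFA differed by -0.77 (adjusted p = 8.28e-05). MMP2, the other gelatinase gene, differed by -0.13 (adjusted p = 0.0575). The endothelial genes KDR and PECAM1 were under the background in both lines, with KDR at 3.21 in 143B and 3.38 in HOS and PECAM1 at 2.77 and 3.13.

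**Figure D2:**
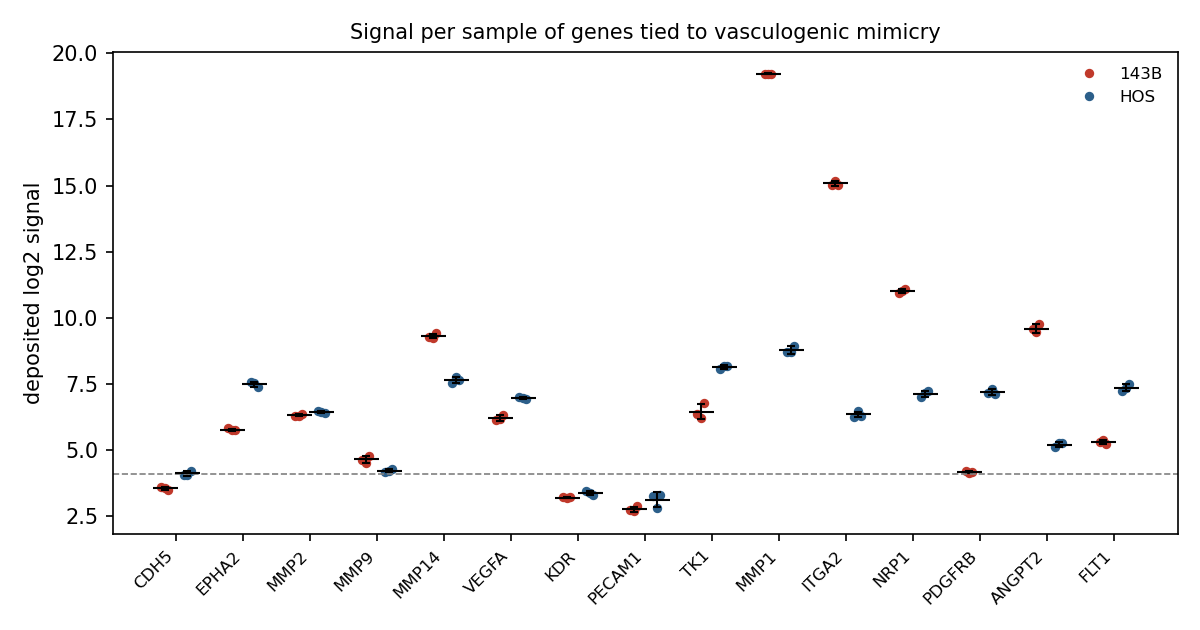
Deposited log2 signal per sample of genes tied to vasculogenic mimicry, of TK1 and of the genes MMP1 and ITGA2, in 143B (red, 3 arrays) and HOS (blue, 3 arrays); the black bars are means with SD and the dashed line is the background level of 4.09. MMP1, ITGA2, NRP1, ANGPT2 and MMP14 lie higher in 143B, EPHA2, FLT1 and PDGFRB lie higher in HOS, and KDR and PECAM1 lie under the background in both.

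Endothelial markers were mostly dim, with 18 of 26 under the background in both lines. Of the 26, 3 were higher in 143B and 1 lower, with 22 not called; camera, which compares a list with other genes, did not call the list (adjusted p = 0.665), while fry, which does not, gave an adjusted p of 0.00360 for a rise. The higher ones were ANGPT2, the vessel-destabilising angiopoietin-2, by 4.39 (SE 0.09), the co-receptor gene ENG by 1.37 and the transcription factor gene ERG by 1.06; the receptor gene FLT1 differed by -2.04 (SE 0.08). Pericyte and smooth muscle markers fell as a list, with 7 of 18 lower in 143B, 0 higher and 11 not called (camera, adjusted p = 0.00251; adjusted p = 0.395 with an estimated correlation). Besides PDGFRB they included TAGLN, which encodes the actin-binding protein transgelin, with a log2 difference of -2.31 (SE 0.06), and TPM2, CALD1 and CNN1, genes of the contractile apparatus, at -2.22, -2.12 and -1.99. Of 41 angiogenic factors and receptors, 6 were higher, 11 lower and 24 not called (camera, adjusted p = 0.880). PDGFRA, the receptor for platelet-derived growth factor A, was higher by 5.61 (SE 0.05, adjusted p = 2.58e-08), opposite to PDGFRB.

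A further question concerned the matrix. Interstitial matrix genes fell as a list in 143B, with 15 of 38 lower, 3 higher and 20 not called (camera, adjusted p = 0.00251; adjusted p = 0.738 with an estimated correlation). COL1A1, the main collagen chain of bone, had a log2 difference of -3.54 (SE 0.09, adjusted p = 6.76e-07), the collagen cross-linking enzyme genes LOXL1 and LOX differed by -2.70 and -1.93, while VCAN, which encodes the proteoglycan versican, was higher by 4.34 (SE 0.11, adjusted p = 6.42e-07). The other higher members were COL6A3, by 2.75, and THBS1, by 1.21. Basement membrane genes went both ways, with 4 of 28 higher, 3 lower and 21 not called (camera, adjusted p = 0.715). LAMB1, a laminin chain gene, was higher by 1.68, as were SMOC1, HSPG2 and PXDN by 1.36, 1.17 and 1.11, and the linker genes NID1 and NID2 differed by -1.57 and -1.33, and the netrin gene NTN4 was 4.01-fold lower. Of 41 matrix proteases and inhibitors, 5 were higher, 6 lower and 30 not called (camera, adjusted p = 0.880). Besides MMP1 and MMP14 the higher ones were the protease genes MMP16 and ADAM19, by 1.96 and 1.79, and the inhibitor gene TFPI2, by 1.38, while PLAT, which encodes tissue plasminogen activator, differed by -1.97 (SE 0.08). Among 25 integrin subunits, 4 were higher, 0 lower and 21 not called (camera, adjusted p = 0.560), with 12 under the background in both lines. Next to ITGA2 these were ITGA1, another collagen-binding subunit, by 3.32 (SE 0.09), the laminin-binding ITGA6 by 2.19 and ITGA10 by 1.02.

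**Figure D3:**
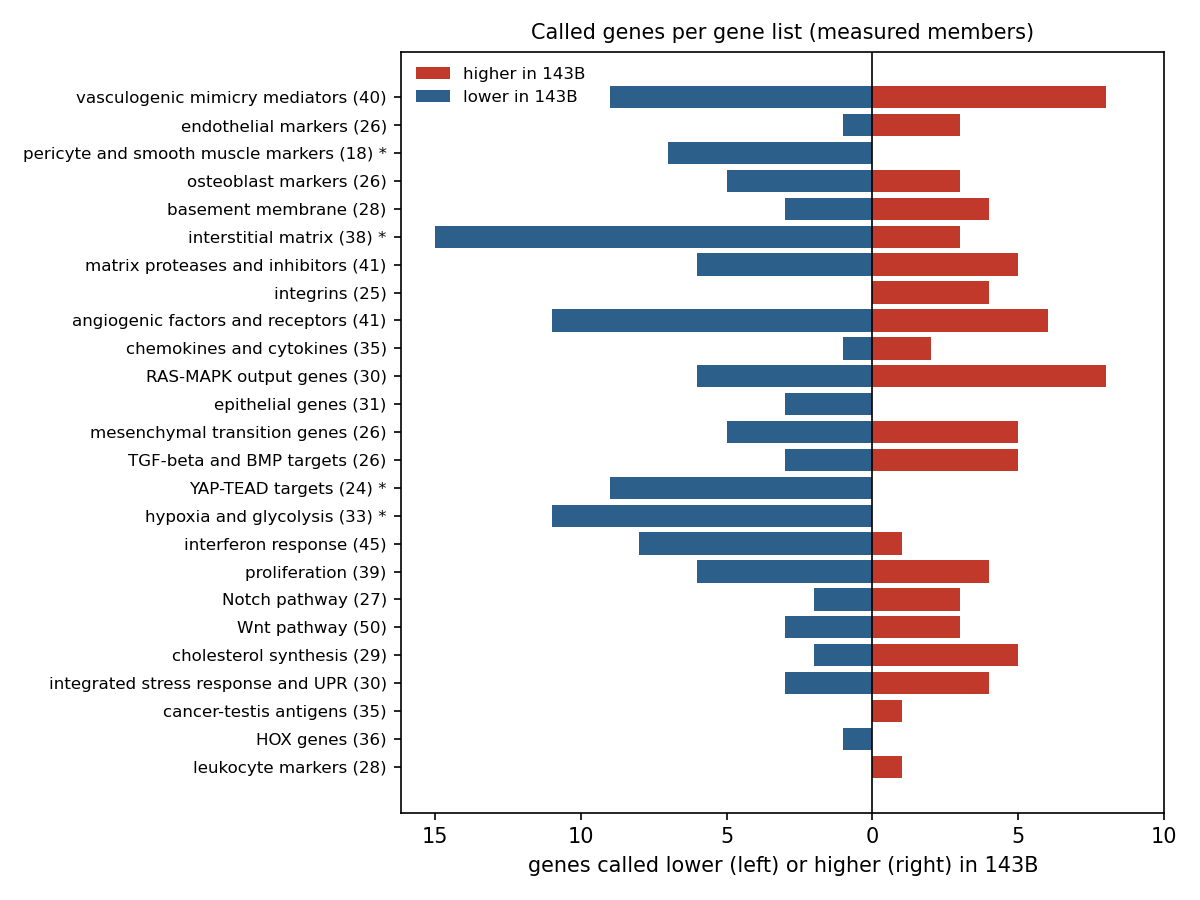
Number of genes called higher (red, right) or lower (blue, left) in 143B against HOS in each of the 25 gene lists, with the number measured in parentheses; an asterisk marks the 4 lists called by camera. In the lists of YAP-TEAD targets, hypoxia and glycolysis, and pericyte and smooth muscle markers, 0 members were higher.

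Signalling outputs were compared next. YAP-TEAD targets, genes switched on by the transcriptional co-activator YAP, fell most clearly as a list, with 9 of 24 lower in 143B, 0 higher and 15 not called (camera, adjusted p = 5.63e-05; adjusted p = 0.395 with an estimated correlation). CCN2, the connective tissue growth factor gene, had a log2 difference of -2.26 (SE 0.05, adjusted p = 3.84e-07) and FJX1 of -1.80 (SE 0.09). The RAS-MAPK output genes split, with 8 of 30 higher, 6 lower and 16 not called (camera, adjusted p = 0.134). IER3, an immediate early gene, was higher by 3.36 (SE 0.19). HMGA2, a chromatin architectural gene, was under the background in HOS and at least 9.01-fold higher in 143B, and SERPINB1 differed by -1.90. TGF-beta and BMP targets had 5 of 26 higher, 3 lower and 18 not called (camera, adjusted p = 0.300). TGFBI, a secreted adhesion protein gene, was higher by 4.64 (SE 0.09), ID1, INHBA and SMAD7 by 3.08, 1.45 and 1.03, and ID3, an inhibitor of DNA binding, was under the background in HOS and at least 8.0-fold higher in 143B. The lower ones included CCN2 and TGFB1, the latter close to the 2-fold minimum.

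Mesenchymal transition genes had 5 of 26 higher, 5 lower and 16 not called (camera, adjusted p = 0.740), with CDH11, the osteoblast cadherin gene, higher by 4.06 (SE 0.15), PRRX1 and TCF4 by 2.21 and 1.84, and LOX and AXL at -1.93 and -1.58. TWIST1, a transcription factor gene of the transition, was also lower. The remaining called members were TGFBI, SNAI1 at 1.08, SPARC at -1.78 and S100A4 at -1.04. Epithelial genes had 3 of 31 lower, 0 higher and 28 not called (camera, adjusted p = 0.552), namely the desmosome genes DSP, at -3.55 (SE 0.06), and PKP2, at -1.80, and EPCAM, at -1.54. In the Notch pathway, 3 of 27 genes were higher, 2 lower and 22 not called (camera, adjusted p = 0.552). NUMB, an inhibitor of Notch, was higher by 1.69, the co-activator genes MAML3 and MAML2 by 1.41 and 1.37, and the receptor gene NOTCH2 and the feedback gene NRARP differed by -1.53 and -1.09. In the Wnt pathway, 3 of 50 were higher, 3 lower and 44 not called (camera, adjusted p = 0.880). The transcription factor gene LEF1 was higher by 1.68, SFRP1 by 1.49 and FZD8 by 1.26, and LGR4, a receptor that enhances Wnt signalling, DKK3 and FZD2 differed by -1.62, -1.53 and -1.14.

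Among metabolic and growth programmes, genes of hypoxia and glycolysis fell as a list, with 11 of 33 lower in 143B, 0 higher and 22 not called (camera, adjusted p = 0.00251; adjusted p = 0.738 with an estimated correlation). SLC2A1, the glucose transporter GLUT1 gene, had a log2 difference of -2.90 (SE 0.08, adjusted p = 7.15e-07), NDRG1 of -2.29 (SE 0.06) and HK2, a hexokinase gene, of -1.95. In cholesterol synthesis, 5 of 29 were higher, 2 lower and 22 not called (camera, adjusted p = 0.630). MSMO1, a sterol oxidase gene, was higher by 2.21 and the fatty acid desaturase gene SCD by 1.61, and EBP and ACAT2 differed by -2.55 (SE 0.04) and -2.25 (SE 0.13). Of 30 genes of the integrated stress and unfolded protein responses, 4 were higher, 3 lower and 23 not called (camera, adjusted p = 0.980). PHGDH, the first enzyme of serine synthesis, was higher by 4.62 (SE 0.08, adjusted p = 2.22e-07), VLDLR, EDEM1 and SEL1L by 2.11, 1.16 and 1.11, PPP1R15A and ATF4 differed by -1.64 and -1.31, and DDIT4, an inhibitor of mTOR signalling, was 4.01-fold lower. Of 39 proliferation genes, 4 were higher, 6 lower and 29 not called (camera, adjusted p = 0.420). After quantile normalization the proliferation list was called higher (adjusted p = 0.0213), and likewise after cyclic loess, an alternative chosen after seeing the data (adjusted p = 0.0132). Over 17 alternatives its adjusted p ranged from 0.0132 to 0.662. TK1, the thymidine kinase gene whose activity 143B lacks, was at 6.46 ± 0.29 in 143B and 8.14 ± 0.07 in HOS (SD, n = 3), a log2 difference of -1.67 (SE 0.14, adjusted p = 7.04e-05). The replication clamp gene PCNA differed by -1.48, and the mitotic regulator gene FOXM1, CENPE, UBE2C and MCM3 were higher by 1.32, 1.03, 1.01 and 1.01.

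The last lists described lineage and immune genes. Osteoblast markers had 3 of 26 higher, 5 lower and 18 not called (camera, adjusted p = 0.665). CDH11 was higher, as were the osteopontin gene SPP1 by 2.63 and DLX5 by 1.04, and the bone alkaline phosphatase gene ALPL, SPARC, MSX1 and COL1A2 differed by -1.36, -1.78, -1.19 and -1.16 next to COL1A1. Of 45 interferon response genes, 8 were lower, 1 higher and 36 not called, and the list missed its threshold narrowly (camera, adjusted p = 0.0507; adjusted p = 0.738 with an estimated correlation). Without replicate 3 of 143B it was called lower (adjusted p = 0.0442), as it was without replicate 2 of HOS (adjusted p = 0.0415). Over 17 alternatives its adjusted p ranged from 0.0132 to 0.145, with 7 of them calling it. The antigen presentation genes HLA-B, B2M and HLA-C differed by -1.94, -1.88 and -1.45. The guanylate-binding protein gene GBP1 was under the background in 143B and at least 8.61-fold higher in HOS, while IFITM3, a membrane protein that blocks virus entry, was higher in 143B by 1.63 (SE 0.07).

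Chemokines and cytokines had 2 of 35 higher, 1 lower and 32 not called, with 25 under the background in both lines (camera, adjusted p = 0.765). The monocyte attractant gene CCL2 and the inflammatory cytokine gene IL1A were under the background in HOS and at least 7.89-fold and 3.35-fold higher in 143B, and LIF was under it in 143B and at least 1.55-fold higher in HOS. Leukocyte markers served to show foreign cells, and 25 of 28 were under the background in both lines. The only called member was CD68, a lysosomal membrane protein gene, higher in 143B by 2.63 (SE 0.05), and 27 were not called (camera, adjusted p = 0.880). Among 35 cancer-testis antigens PRAME alone was called, higher by 1.43 (SE 0.08), with 34 not called (camera, adjusted p = 0.980). Among 36 HOX genes HOXA5 alone was called, under the background in 143B and at least 2.58-fold higher in HOS, with 35 not called (camera, adjusted p = 0.954).

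Camera called 4 of the 25 lists, all lower in 143B, and called 0 with an estimated correlation, under which 2 lists had an unadjusted p below 0.05. The counts adjusted over the list alone equalled those over all genes tested in each of the 25 lists. A list's median and mean differed in sign in 9 lists, and its mean and camera's direction in 8, none of them a called list. Among coding genes above the background, the share called lower rose with the signal, from 2.43% in the dimmest of 10 groups to 23.8% in the brightest. The 4 called lists stayed called with genes under the background left out, but lists were not compared with genes of the same signal.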

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

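All tests of explanations in this part were chosen after the result was seen. Control rows, which entered none of the comparisons, differed between the lines. On the log2 scale, 143B minus HOS, the poly-A control dap differed by -4.87, phe by -3.36 and thr by -3.74, and the ERCC spike-in rows ERCC-00014, ERCC-00099 and ERCC-00145 by -7.46, -3.58 and -3.78, each above the background in HOS. These were the 3 of 92 ERCC rows that differed by 1 or more. Among 2872 other control rows, which carry no gene symbol, 1261 differed by 1 or more. Of the 40310 main rows without a gene symbol, 3837 were called, 2846 higher and 991 lower in 143B.

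The poly-A controls are spiked into RNA before labelling. A candidate explanation is that they were added to the HOS RNA and not, or at a far lower amount, to the 143B RNA: they differed by a median of -3.55, while the hybridization controls, added after labelling, differed by a median of -0.20. Whether a separate labelling run of each line is also a source of the differences in genes stays open, since no run is known to hold both lines, and batch and line cannot be told apart. Across background probe sets and hybridization controls the largest difference was -0.405. All 23 background probe sets were lower in 143B (-0.405 to -0.024, median -0.109), and the 92 ERCC rows had a median of -0.146. Normalization between arrays removes a shift of a whole array, and a bias on single transcripts would not show in these controls. The biological difference between the lines stays open as a source beside a separate labelling run.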

How the results depend on the processing

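Tests with cyclic loess, with coding genes only and with genes outside the chromosome segments were chosen after the results were seen. The 69 named genes kept their direction and their side of the threshold in all 1168 alternative values, with a largest change of 1.19 (log2). Of these, 61 were called, and most were picked for a large difference in these same data, which favours such stability. Genes named as further examples were not in this check, and those close to the 2-fold minimum may change sides. The count of 2808 genes ranged from 2793 to 2847 with a sample left out, and was 2726 after quantile normalization (50.1% of them higher, against 43.9%), 2727 after cyclic loess (51.9% higher) and 2871 after median centring, with 2543 genes shared with the main result under quantile normalization. It moved by over 1.5 times where the rule itself changed: 6870 rows were called among all rows that are not controls (4159 higher, 2711 lower), 11763 genes with no minimum on the difference (5280 higher, 6483 lower) and 1662 by TREAT (730 higher, 932 lower). The replicate numbers did not pair the samples (same-number correlations of deviations 0.0538, 0.0325 and 0.0759, and not every sample correlated best with its own number); with the number as a block 2808 genes were called.

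The count of 4 lists was 0 with an estimated correlation, where pericyte and smooth muscle markers and YAP-TEAD targets had an adjusted p of 0.395 and interstitial matrix and hypoxia and glycolysis of 0.738. It was 17 by fry and 25 by its mixed test, which do not compare a list with other genes. Over the 17 alternatives at the preset correlation the 4 lists stayed called, with adjusted p at most 0.0301, and the interferon list was called in 7 and proliferation in 2. For mediators of vasculogenic mimicry fry gave 0.00970 (lower), and the mixed test, which gives no direction, 1.49e-07. Fry turned the direction of matrix proteases (0.00762, higher), angiogenic factors (0.00461, higher) and the Wnt pathway (0.00360, lower), none called by camera; the cause was not tested. The 6 samples make 10 splits into 3 and 3, too few for a share under 0.05: the real split, 1 of the 10, called 2808 genes and 4 lists, and the highest of the others 0 genes and 2 lists. Every other split mixes the lines in each group, which adds their difference to the spread. A low count of genes there was therefore largely fixed in advance. Signal over background limits what can be said of the genes under 4.09 in both lines.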

Other observations

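The enrichment, chromosome and short RNA tests in this part were chosen after the differences were seen, except the tests of rows without a symbol, whose bounds were set before those rows were looked at. Genes of the actin stress fibre, the contractile bundle that ties a cell to its matrix, were enriched among those lower in 143B: 17 of 37 were lower where 4.31 would be expected by chance (adjusted p = 0.000207). They included the non-muscle myosin heavy chain genes MYH9 (log2 difference -3.47, SE 0.06) and MYH10 (-2.08, SE 0.08), the cross-linker gene ACTN4 (-3.05, SE 0.11) and the focal adhesion gene VCL (-1.58, SE 0.10), beside MYL9. The proteasome, the complex that degrades ubiquitin-tagged proteins, had 20 of 61 genes lower where 7.11 would be expected (adjusted p = 0.00318), with PSMA1 at -2.31 (SE 0.13). The share of coding genes called lower rose with the signal, from 2.43% in the dimmest of 10 equal groups to 23.8% in the brightest, and that called higher rose less, from 2.43% to 9.48%; proteasome genes are bright. Against genes of the same signal group, 11.6 lower proteasome genes would be expected (permutation p = 0.0046) and 4.87 lower stress fibre genes (permutation p = 0.0001, the smallest that 10000 draws can give), for terms already picked by their enrichment. The enrichment tests and the random draws treat genes as independent. Genes of a shared structure need not be, so these p-values may be too small. Among genes higher in 143B, asparagine-linked protein glycosylation had 16 of 84 higher where 6.24 would be expected (adjusted p = 0.0367), but also 8 lower, and its median over all members was 0.12. The higher members include FUT8, a fucosyltransferase gene, at 2.80 (SE 0.05). The term for taste perception had 10 of 12 genes higher (adjusted p = 1.20e-06), LEF1 and otherwise bitter taste receptor genes, but these are similar genes that neighbour each other on chromosome 12. Cross-hybridisation between them was not checked, so they are not shown to be separate measurements. The medians over all members of the stress fibre and proteasome terms, -0.62 and -0.55, kept their sign under quantile normalization, median centring and cyclic loess.

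MicroRNA hairpin rows of the miR-548 family were higher in 143B in 33 of 40 genes above the background, with a median of 2.95, and 0 were lower. Of 360 other microRNA genes above the background, 53 were higher and 2 lower, with a median of 0.19 (quartiles -0.08 and 0.66). Members of the miR-548 family have similar sequences and cross-hybridisation was not checked, so their rows are not shown to be separate measurements.

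Several classes of short non-coding RNA had median differences below 0. These were -0.56 for 125 C/D-box snoRNAs, -0.52 for 77 H/ACA-box snoRNAs, -0.82 for 147 rows of spliceosomal snRNA and -0.48 for 224 rows of 5S rRNA. Their sign was the same under each of the 3 other scalings. All classes, Y and vault RNAs included, were set by gene symbol, so pseudogene copies were not sorted out. Cross-hybridisation between similar rows was not checked, so they are not shown to be separate measurements. Members went both ways: 29 snRNAs were called higher and 64 lower (quartiles -1.84 and 0.52), 8 and 44 C/D-box snoRNAs, 3 and 29 H/ACA-box snoRNAs, and 5 and 63 rows of 5S rRNA. Most snoRNAs are cut from the introns of host genes. Of the 73 lower snoRNAs, 43 lay inside a measured host gene and had a median of -2.14. Their 38 hosts had a median of -0.134 (quartiles -0.49 and 0.07), with 2 of those hosts called lower. A lower host signal was thus argued against for these 43 as a set, but 3 of them lay in hosts called lower. For those 3 and for the other 30 snoRNAs a lower host signal stays open. Host signal is a level of RNA, so it speaks only indirectly to lower transcription of the hosts. A host at the top of the scale cannot show a fall. NCL, the host of SNORD82 and SNORA75, had a difference of 0.0, as such a host would. Whether it or other hosts lay at the top was not checked. Lower recovery or labelling of all short RNAs in the 143B samples stays a possible explanation, since Y and vault RNAs had a median of 0.275 with quartiles of -0.08 and 0.51, which decides nothing; microRNA rows were left out of the test because hairpins lie in longer transcripts, and counting them, the miR-548 family above all, would speak against that explanation. The members called higher would need a rise of their own, and a difference between the lines also stays open.

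Rows of neighbouring genes differed together in 8 segments, but those on chromosomes 9 and 12 consist mostly of similar gene copies, among them the taste receptors, that are not shown to be separate measurements, and the random gene orders do not allow for this. On chromosome 1, from 111659954 to 120855681 (GRCh37), 36 of 49 coding genes above the background were higher in 143B and 2 lower, with a median of 1.60; they include NRAS, which encodes a RAS GTPase (3.16, SE 0.07), WARS2 (4.26), PHGDH and TBX15. On chromosome X, from 39909068 to 47431320, 19 of 23 were lower and 0 higher, with a median of -1.63, including the deubiquitinase gene USP9X (-4.47, SE 0.08), UBA1 (-3.38), KDM6A (-2.51) and DDX3X (-2.34). Elsewhere on chromosome X, from 20142636 to 25015103, 9 of 13 coding genes were lower and 1 higher. From 77385245 to 92928682, 8 of 12 were higher and 1 lower. Without the genes of all 8 segments 2691 genes were still called.

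Chance placement was argued against for the chromosome 1 segment and for the chromosome X segment of 23 genes. Each had a permutation p of 0.001, the smallest that 1000 gene orders can give. A gain of the chromosome 1 segment and a loss of that chromosome X segment in 143B are hypotheses that may explain such runs. They were tested on rows without a symbol inside both segments. The 30 such rows on chromosome 1 differed from those on all chromosomes by 0.094 (bootstrap range -0.21 to 0.92), and the 19 on chromosome X by 0.106 (-0.52 to 0.56), which is not the sign of a loss. Neither range reaches the segment's own median, so a change of that size was not seen in these rows; but both reach, on chromosome X barely, the 0.5 set beforehand as the least that copy number would give, and the rows are few and dimmer than the coding genes (median level 4.95 against 8.52 on chromosome 1, 5.90 against 7.63 on chromosome X), so a gain or loss stays open, as does shared regulation of neighbours, which was not tested.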
